A study of Sus scrofa with 24 samples.

How the data were processed

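Reduced representation bisulfite sequencing, which reads cytosine methylation in the CpG-rich part of the genome, was done on hypothalamus DNA of 24 pigs aged 21 days. Per the labels, 13 animals were controls (7 females and 6 males) and 11 belonged to the arm called viral (5 females and 6 males). The labels give no litter, dam or batch, so animals that shared a dam could not be accounted for, and p-values treat each animal as independent. Animals are named by group and number; the numbers are unique to an animal and pair no samples.

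The deposited files hold, per the file headers, whole-number counts of cytosine calls in fixed windows of 100 kb: all calls (coverage), methylated calls and unmethylated calls. Per the labels, the authors' tools were bcl2fastq 2.20, Trim Galore 0.6.10, Bismark 0.22.3 and HISAT2, with the genome build susScr11; the step that summed calls into windows is not given in the sources used here. Methylated plus unmethylated calls equalled coverage in every listed window, and no listed window had fewer than 100 calls. Coordinates are 1-based on that build. Gene symbols came from a RefSeq gene table of the assembly Sscrofa11.1, the same assembly, by overlap of gene and window; protein-coding genes with a symbol count as named, and LOC or Ensembl identifiers do not. A window can hold several genes, its value belongs to none of them alone, and positions of exons, promoters or CpG islands were not used here.

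In all, 22113 windows were listed in at least 1 animal and 14221 in all 24. A window entered the tests when it had at least 10 calls in every animal, which kept all 14221 (13586 on autosomes, 378 on X, 16 on Y, 1 mitochondrial and 240 on unplaced sequence), of which 11565 overlapped a named gene. Total calls per animal ran from 33105863 to 61620653, and the median window had 1823.5 calls. Calls from the same fragment are not independent, so the spread between animals, not the number of calls, set the precision.

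Methylated and unmethylated counts were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with an intercept for each animal, 1 term for each of the 4 groups, and both columns of an animal scaled to the same library size. The fitted change is in log2 odds of methylation, given with its standard error (SE). The contrasts were viral against control averaged over the sexes, male against female averaged over the arms, viral against control within each sex, and the difference between those within-sex effects. Adjusted p is by Benjamini-Hochberg over all windows of a contrast, with a threshold of 0.05, two-sided. Differences in percentage points are between group means and are averaged in the same way as the contrast, so they can differ a little from the difference of the means over all animals of an arm.

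Methylation per animal was the share of all calls in tested windows that were methylated. It was compared by two-sided permutation of labels within sex or within arm, with 100000 resamples for the infection and sex contrasts and exact enumeration within a sex and for the interaction. Benjamini-Hochberg values were taken over the exact p of 35 such tests. Effects in females and males were compared by correlation across windows, set against 100 relabellings; windows are not independent replicates.

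Gene groups were tested with camera in limma 3.58.1, which compares a group with all other windows, on log2 of methylated plus 1 over unmethylated plus 1, with a preset correlation of 0.01, then with an estimated correlation and with fry. The 24 lists held 680 entries, of which 663 matched the gene table and 617 lay in tested windows. They covered neuropeptides, neuroendocrine receptors, the glucocorticoid axis, hypothalamic development, glutamate, GABA and monoamine signalling, antiviral and cytokine signalling, antigen presentation, DNA methylation machinery, imprinted genes, neurodevelopmental disorder genes, the circadian clock, energy balance, axon guidance, and protocadherin and HOX clusters. Marker lists of microglia, astrocytes, oligodendrocytes and their precursors, neurons, vessels, ependyma and tanycytes, and anterior pituitary were added for the other cell types a dissected hypothalamus could hold.

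Groups, lists, contrasts, tests, thresholds, the naming rule and a first set of other settings were fixed before the data were examined. By that rule, each contrast names, among windows past the threshold that hold a gene symbol, the 10 with the largest rise and the 10 with the largest fall in percentage points, for sex the 6 each way on autosomes and the 4 each way on X. Where fewer than 10 passed, it names those that passed and the windows with the smallest p up to 10. It adds up to 4 members of each list with the smallest p for infection, of which the first ones are given here, any member past the threshold in the difference between sexes (0 passed), and always DNMT1, DNMT3A, DNMT3B, TET1, NR3C1, AVP, OXT, CRH and POMC. Windows named outside the rule are said to be so, and some windows that the rule names are not reported here.

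Those settings were other coverage minimums and none, the likelihood ratio test of edgeR, DESeq2 1.42.0, limma with offsets of 1 and 5, separate library sizes for methylated and unmethylated calls, an adjusted p of 0.10, autosomes alone, depth or overall methylation as a covariate, fits within a sex on only the groups compared, and each animal left out in turn. For overall methylation they were the mean over windows, and for the lists an estimated correlation, an offset of 5 and autosomes alone. Alternatives chosen after seeing the data were a minimum of 500 calls, leaving out control female 5 together with the methylation covariate, exact enumeration for the infection and sex tests of overall methylation, the same window weights in every animal, X minus autosomes, fry as a replacement for camera, limma for the comparison of female with male effects, a covariate for libraries with few calls in a window of chromosome 9, and fits on the other 19 libraries alone. The permutation tests and tables used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and the window, list and split tests used R.

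The window test was tested on simulated data for the infection contrast, with counts drawn for the 14221 windows at the real depths, each animal's overall shift kept, and 1 common dispersion of 0.0658. It recovered 60 of 100 windows whose odds were changed 2-fold and 100 of 100 changed 4-fold, with 0 false calls. The 200 windows were changed at once, which eases the adjusted threshold for each, and every window had the same dispersion. The shares recovered and the 0 false calls therefore need not hold in the real data, where few or no windows may change. The median SE was 0.264 in the simulation.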

Results

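Cytosine methylation was measured by reduced representation bisulfite sequencing in the hypothalamus of 24 pigs aged 21 days, in a study of offspring after maternal infection. The arms were control (7 females, 6 males) and viral (5 females, 6 males), and values are methylated calls as a percentage of all calls in 100 kb windows of the build susScr11. Total calls per animal ran from 33105863 to 61620653. Of the 14221 windows listed in all 24 animals, the median window was 57.5% methylated. Calls on sex chromosomes followed the labels: 7 Y windows were listed in all males and in no female, and X windows took 3.61% ± 0.229 of calls in females (SD, n = 12) and 1.104% ± 0.0517 in males (SD, n = 12).

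The first comparison asked whether the hypothalamus of offspring in the viral arm differed in methylation from that of controls. The smallest p belonged to a window over TMEM178B (chromosome 18, 8400001 to 8500000), at 63.6% ± 7.79 in controls (SD, n = 13) and 77.6% ± 5.54 in the viral arm (SD, n = 11). All 11 viral animals lay above the control mean there, and the difference of 13.9 points was a log2 odds change of 0.99 ± 0.21 (SE; adjusted p = 0.874 by edgeR). A window over SRD5A2, the steroid reductase that makes dihydrotestosterone, was at 10.1% ± 5.15 in controls and 18.96% ± 6.12 in the viral arm, and 10 of 11 viral animals lay above the control mean. SYNE2, which links the nucleus to the cytoskeleton, lay in a window at 41.6% ± 6.77 and 53.9% ± 10.7, and the X-linked gene EDA, a signal in skin and tooth development, in a window at 16.5% ± 5.41 and 27.6% ± 10.03 (SD, n = 13 and 11). None of these passed the test. Windows were named by p or by size of difference, so counts of animals beyond the other group's mean, here and below, are no separate support.

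The other windows with the smallest p were all higher in the viral arm. Windows over the zinc transporter gene SLC39A11 and over AAMDC with INTS4 were higher by 5.05 and 4.21 points. A window holding GTF3C3, C15H2orf66 and PGAP1 was higher by 9.91 points, one holding PCMT1, NUP43 and the Hippo pathway kinase gene LATS1 by 4.796, ZNF609 by 2.65, and PPP4R4, a phosphatase subunit gene, by 9.86 points. Adjusted p was 0.928 for each of the 6.

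No window passed for infection: edgeR's quasi-likelihood test called 0 of 14221, with 419 at an unadjusted p under 0.05 (258 to 877 with 1 animal left out, 644 with overall methylation as a covariate), and limma called 0 with 457. Without any difference, a share of 0.05 of the windows would lie under that p on average. Both 419 and 457 of 14221 are smaller shares, but windows are not independent and such counts vary widely between splits of the animals. By limma, 35 of 100 splits gave as many as 457, with a median of 323 and a highest of 5101 in the other splits. The counts of 419 and 457 are therefore no sign of remaining differences. DESeq2 and edgeR's likelihood ratio test each called the TMEM178B window alone (adjusted p = 0.0477 and 0.0360). Without a coverage filter, 1 window of X starting at 118500001, listed in only part of the animals and with only uncharacterised loci, was called and was lower in the viral arm (log2 odds -4.13, adjusted p = 0.0174). The median window was higher in the viral arm by 0.13 log2 odds, a shift that separate library sizes for methylated and unmethylated calls turned to -0.04, so the differences of single windows are to be read against it.

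**Figure D1:**
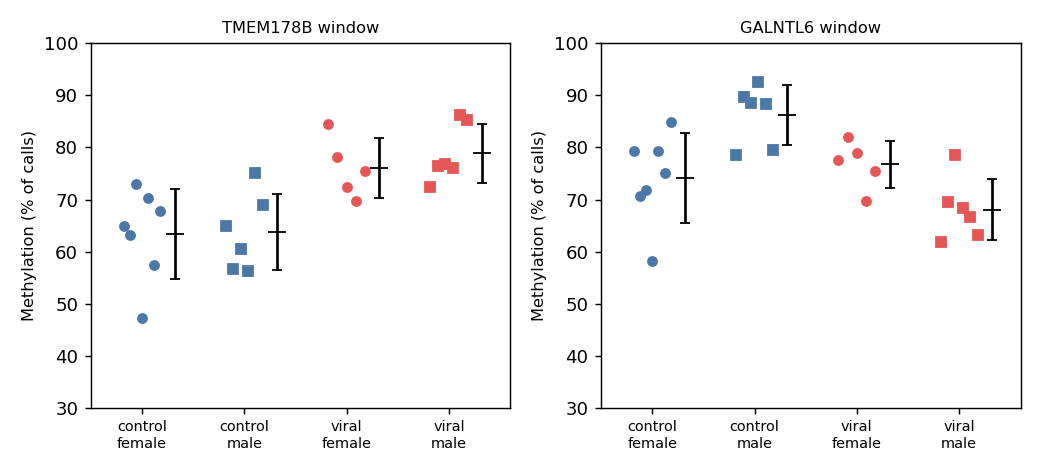
Methylation (% of calls) of each animal in the windows over TMEM178B (left) and GALNTL6 (right), by group. Points are animals, with the group mean and SD beside them; the viral groups averaged 76.1% and 78.9% over TMEM178B and the control groups 63.4% and 63.8%, while over GALNTL6 control males averaged 86.2% and viral males 68.1%.

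Methylation over all tested windows was 53.6% ± 7.81 in controls (SD, n = 13) and 56.4% ± 4.97 in the viral arm (SD, n = 11). The difference averaged over the sexes was 2.85 points (p = 0.348, permutation test; Benjamini-Hochberg 0.900 over 35 tests), smaller than the spread between animals. Control female 5 stood apart at 31.7%, and without that animal the difference was 1.11 points. As a mean over windows, and also with the same window weights in every animal, it was 1.86 points, and without control female 5 these were 0.696 and 0.659 points.

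**Figure D2:**
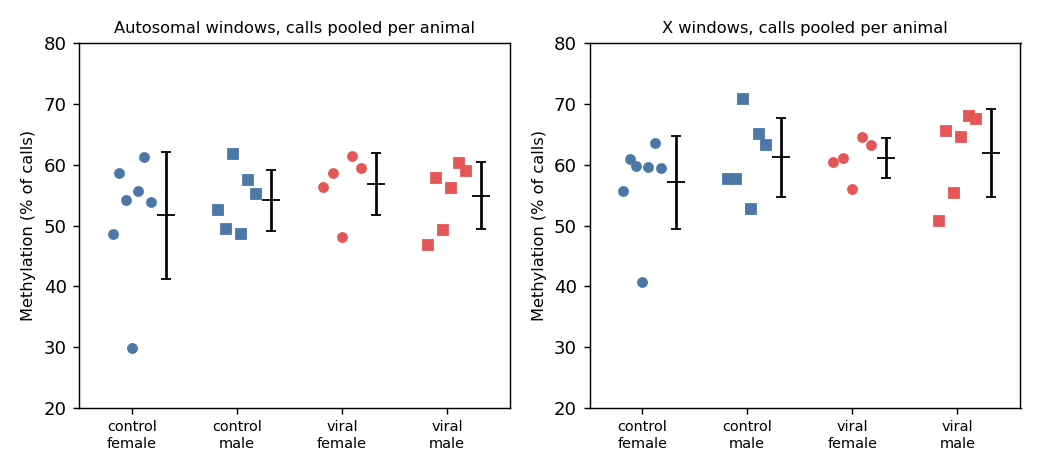
Methylation (% of calls) of each animal over autosomal windows (left) and X windows (right), by group, with the group mean and SD beside the points. Control female 5 is the low point of its group, at 29.8% on autosomes and 40.6% on X.

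Libraries also parted in the 100 kb window of chromosome 9 that ends at 4800000 and holds no named gene, a split noticed in the data. In 19 libraries it held 6214 to 53665 calls at 1.41% to 7.42% methylation, and in 5 it held 365 to 525 calls at 76.2% to 83.5%. The 5 were control male 13, viral females 22 and 24 and viral males 21 and 23, so 4 of 5 were viral. By number, control male 13 was the last of the controls, and 21 to 24 were the last 4 of the viral arm. Mitochondrial methylation was 7.997%, 7.52%, 7.54%, 7.22% and 12.8% in these 5, in that order, and 8.97% to 10.8% in the other 19. Within the 19, edgeR again called 0 windows for infection (141 at an unadjusted p under 0.05), the overall difference was 0.665 points (p = 0.864, exact permutation test), which ran from -1.08 without control female 5 to 2.10 without viral female 18, and the median window shift 0.02 log2 odds. With the split as a covariate the count was also 0, with 219 at an unadjusted p under 0.05. The 5 libraries hold 1 control, so no comparison was made within them.

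**Figure D3:**
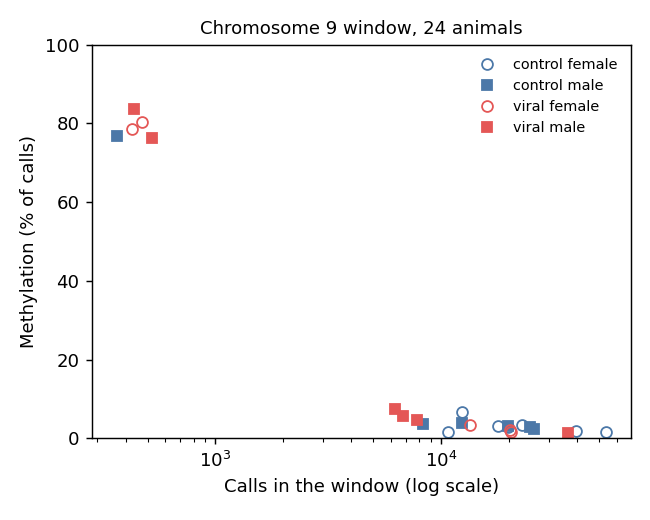
Calls (log scale) and methylation (% of calls) of each animal in the chromosome 9 window, by group. The 5 libraries at upper left hold 365 to 525 calls, and the other 19 hold 6214 to 53665.

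Neuropeptide genes had the smallest p of the 24 gene lists for infection. Of 30 measured members in 31 windows, 0 passed over all windows and 0 adjusted over the list alone, and the windows' median change was 0.18 log2 odds against 0.13 for all windows (camera p = 0.00608, adjusted p = 0.146 over the lists; p = 0.476 with an estimated correlation). The window over CARTPT, an appetite-suppressing peptide gene, was at 50.5% ± 10.3 in controls and 61.8% ± 9.22 in the viral arm (SD, n = 13 and 11), and that of CCK, shared with TRAK1 and LYZL4, at 75.1% ± 3.28 and 79.3% ± 5.03. Antiviral and cytokine genes (53 measured, 0 passing) had a median change of 0.17 and camera p = 0.0497 (adjusted p = 0.470; p = 0.692 with an estimated correlation). Among them, the window of the kinase gene JAK1 was higher by 3.02 points, in 11 of 11 viral animals above the control mean. No list passed an adjusted p of 0.05 by camera with either correlation or by fry, in any of the 5 contrasts.

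Among lists of hormone and stress genes, 0 members passed, over all windows or adjusted over the list alone; the adjusted p given for each list is by camera over the 24 lists. Neuroendocrine receptors (33 measured, adjusted p = 0.758) included IGF1R at 85.9% ± 3.34 and 89.8% ± 3.20 and the estrogen receptor gene ESR2 at 27.4% ± 6.42 and 33.5% ± 5.94 in control and viral animals. The glucocorticoid axis (19 measured, adjusted p = 0.798) included NR3C1, the glucocorticoid receptor gene, whose windows differed by 4.29 points and -0.791 points (the latter from -1.51 to -0.190 with 1 animal left out), and its coactivator gene NCOA1, by 8.31 points. Hypothalamic development (31 measured, adjusted p = 0.798) included SIX6, higher by 6.02 points, and ARNT2, by 2.58 points. Energy balance and insulin signalling (30 measured, adjusted p = 0.617) included FTO, higher by 4.96 points. The anterior pituitary list (12 measured, adjusted p = 0.758) included CGA and FSHB, hormone subunit genes whose windows were higher by 4.62 and 7.40 points.

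For neurotransmission and neuronal wiring, 0 members passed either adjustment. Glutamate signalling (33 measured, adjusted p = 0.758) included the receptor genes GRID1, higher by 9.29 points, and GRM5, by 8.33 points. GABA signalling (19 measured, adjusted p = 0.758) included GABBR2, at 3.74 points and in 11 of 11 viral animals above the control mean. Monoamine signalling (32 measured, adjusted p = 0.758) included the dopamine receptor gene DRD2, at 5.11 points, and the serotonin receptor gene HTR1A, at -5.31 points. Axon guidance and adhesion (38 measured, adjusted p = 0.47) included NCAM1 and NRP2, at 5.66 and 4.29 points. Neurodevelopmental disorder genes (48 measured, adjusted p = 0.758) included NRXN3 and FOXP1, at 5.51 and 4.20 points. The median change of these windows was above 0 in each list, while camera, which compares a list with other windows, placed the glutamate, monoamine, axon guidance and disorder lists below them, as it did the neuron, ependyma and tanycyte, imprinted, and protocadherin and HOX lists.

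Cell type markers were not called either, with 0 members passing in each list. Adjusted p by camera was 0.617 for microglia (13 measured, SALL1 and CSF1R higher by 4.84 and 3.13 points), 0.758 for astrocytes (14 measured, SLC1A3 and SLC4A4 higher by 4.27 and 7.01) and 0.869 for oligodendrocytes (17 measured, SOX10 and ASPA higher by 3.72 and 2.70). It was 0.824 for oligodendrocyte precursors (12 measured, PDGFRA and MEGF11 higher by 5.83 and 5.28), 0.758 for neurons (19 measured, INA higher by 5.35) and 0.758 for vessels (17 measured, PECAM1 and KCNJ8 higher by 3.54 and 6.49). It was 0.758 for ependyma and tanycytes (12 measured, DNAH9 at 7.48 and CFAP54 at -3.14 points). Antigen presentation and complement (29 measured, adjusted p = 0.758) included the class II genes SLA-DQB1, SLA-DQA1 and SLA-DRB1 in a window higher by 7.49 points and their regulator CIITA, by 4.33 points. Without control female 5 the CIITA and CSF1R windows were higher by only 2.18 and 1.84 points, without viral female 22 the SLC4A4 window by 3.30, and the ASPA window ran from 1.67 to 4.32 points with 1 animal left out. The CSF1R window also holds HMGXB3 and PDGFRB, and PDGFRB is a member of the vessel list.

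The remaining lists concerned the regulation of methylation and gene clusters, with 0 members passing. DNA methylation machinery (25 measured, adjusted p = 0.758) included MBD4, at 6.61 points. Windows holding the maintenance methyltransferase gene DNMT1 differed by 0.650 and 2.86 points, and those holding DNMT3A, a de novo methyltransferase, by 1.28 and 4.05 points, the latter shared with the hormone precursor gene POMC. DNMT3B differed by -0.343 points, and TET1, which oxidises methylcytosine, by 3.80 and 4.94 points. The vasopressin gene AVP was in a window higher by 3.69 points, oxytocin (OXT) by 6.81 and corticotropin-releasing hormone (CRH) by 0.999 points. For the windows of DNMT1, of DNMT3A without POMC, of TET1 with CCAR1, of CRH and of DNMT3B, other settings turned the direction. Imprinted genes (39 measured, adjusted p = 0.864) included DLK1 and L3MBTL1, at 4.51 and 4.87 points. The circadian clock (23 measured, adjusted p = 0.869) included RORA and CSNK1D, at 6.40 and 4.12 points. The protocadherin and HOX list (17 measured, adjusted p = 0.758) included HOXB2 and PCDH1, at 4.48 and 3.85 points. Of the 64 windows named for infection, the difference in 13 turned or moved by over 1.5 times without control female 5. Here these were AVP (1.76 points), CRH (0.337), CSNK1D (2.43), PCDH1 (2.30), TET1 with CCAR1 (2.31), DNMT1 (-0.572 and 1.65), DNMT3A (-0.257, or 2.41 with POMC) and DNMT3B (-1.41). Other animals moved some as far: with 1 animal left out, TET1 with CCAR1 ran from 2.31 to 9.37 points, CRH from -0.236 to 2.26, the first DNMT1 window from -0.572 to 1.97, DNMT3A without POMC from -0.257 to 2.05 and DNMT3B from -1.41 to 0.615.

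The second comparison asked whether the difference between arms depended on sex. In males, a window over GALNTL6, which encodes a protein of the family that starts mucin-type glycosylation, was at 86.2% ± 5.77 in controls and 68.1% ± 5.91 in the viral arm (SD, n = 6 and 6), and all 6 viral males lay below the control mean. The same window was at 74.2% ± 8.61 and 76.8% ± 4.56 in control and viral females (SD, n = 7 and 5). In females, the windows over ACER3, a ceramidase gene, and SNX13 were at 32.5% ± 12.9 and 16.4% ± 3.72 in controls and 56.9% ± 14.99 and 33.05% ± 14.4 in the viral arm. SLC39A11 was higher in viral females by 8.02 points, in 5 of 5 above the control mean. None of these passed: adjusted p by edgeR was 0.451 for GALNTL6 in males, 0.768 for the windows in females, and 0.999 for the difference between the sexes at GALNTL6.

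Other windows with the smallest p for the difference between sexes were those of BRINP2, C2H5orf15, the chloride transporter gene CLCN5, BBS9, NIN with ABHD12B and PYGL, SEMA4F, SLC25A31 with INTU, and PLCL2. In each, the male difference minus the female difference was negative, from -27.3 points for the NIN window to -5.82 for the SLC25A31 window. The median window was itself at -0.21 log2 odds for the difference between sexes and at 0.23 in females. Separate library sizes for methylated and unmethylated calls turned these medians to 0.03 and -0.06. That setting scales out each animal's shift over all windows, so it cannot show whether the shared sign belongs to single windows. The shared sign is to be read against the shift of the median window. Control female 5 lay far below its group over BBS9 (60%), SEMA4F (48.4%) and BRINP2 (59.5%). Further windows with the smallest p in females lay over SYNE2 (18.5 points), BBS9 (11.1), FNDC3B (7.65), CAPZA1 with ST7L (10.2), SLC27A6 (16.2) and PPP2R5E (13.9). In males they lay over TMEM178B (15.1 points), NAV3 (5.19), CLCN5 (-6.51), LAMP2 with ATP1B4 (-8.33), ZNF609 (3.67), PRRG3 (21.8), ITSN2 (4.83), PPP4R4 (12.98) and RUNDC3B (-18.99).

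By edgeR's quasi-likelihood test 0 windows passed for the difference between the sexes, 0 in females and 0 in males, with 245, 657 and 143 at an unadjusted p under 0.05, counts that ran from 148 to 572, 298 to 1660 and 125 to 246 with 1 animal left out. The counts with all animals were each below a share of 0.05 of the 14221 windows, the average without any difference. Windows are not independent, so such counts vary widely and this share alone decides little. With overall methylation as a covariate the counts were 528, 628 and 593, and with separate library sizes 436, 699 and 420. Limma called 0 in each, with 296, 734 and 185. DESeq2 called 0, 0 and 1, as did edgeR's likelihood ratio test, and that 1 was the GALNTL6 window (adjusted p = 0.0262 and 0.00977). Without a coverage filter, the X window starting at 118500001 was called for the difference between the sexes and in males. Overall methylation differed by 4.93 points in females (p = 0.384, exact permutation test), or 1.44 without control female 5, and by 0.784 points in males (p = 0.794, exact permutation test), from -0.340 without control male 11 to 2.36 without viral male 14, and by 0.337 as a mean over windows and 0.407 with the same window weights in every animal, which ran from -0.394 and -0.339 without viral male 21 to 1.45 and 1.54 without viral male 14. The difference between the sexes was -4.14 points (p = 0.516, exact permutation test) and was -0.660 points without control female 5, -2.68 without control male 9 and -2.57 without viral male 14. Within the 19 libraries named above the arms differed by 2.62 points in females and -1.29 points in males, values that ran from -0.861 without control female 5 to 5.49 without viral female 18 and from -3.03 without viral male 17 to 0.596 without control male 9. Across windows, female and male effects correlated at Pearson 0.064 (0.0427 with at least 500 calls) and Spearman 0.069; with limma the Pearson value was 0.054, which 29 of 100 relabellings reached, the real one included.

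The third comparison set males against females and found differences on the X chromosome. Windows of low methylation were higher in females: that over PGK1, a glycolytic kinase gene, and TAF9B was at 35.3% ± 4.20 in females (SD, n = 12) and 9.17% ± 3.36 in males (SD, n = 12). The window of NR0B1, a nuclear receptor gene of adrenal and gonad development, was at 30.6% ± 4.15 and 4.92% ± 3.28, and that of the synaptic scaffold gene CASK at 48.7% ± 9.62 and 25.5% ± 10.1. Windows of high methylation were higher in males: that over LONRF3 and KIAA1210 was at 64.8% ± 4.18 in females and 87.0% ± 4.21 in males, and that over TMLHE, an enzyme gene of carnitine synthesis, at 69.3% ± 6.53 and 88.5% ± 3.96. Every male lay on the same side of the female mean in each of these 5 windows.

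The changes in log2 odds from female to male were -2.47 ± 0.19 for PGK1 (SE; adjusted p = 4.96e-09 by edgeR), -3.28 ± 0.26 for NR0B1 (adjusted p = 1.23e-08), -1.58 ± 0.28 for CASK (adjusted p = 0.00135), 1.88 ± 0.20 for LONRF3 (adjusted p = 8.96e-07) and 1.77 ± 0.19 for TMLHE (adjusted p = 1.23e-06). The window of ZMAT1 and TCEAL2 was higher in females, by -22.5 points from female to male. Those of RNF128 with TBC1D8B and of MAP7D3 with ADGRG4 were higher in males, by 20.9 and 17.3 points. Adjusted p was 1.5e-05, 1.03e-05 and 0.00135 for these by edgeR.

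Of 378 X windows, 27 passed as higher in females and 74 as higher in males. The 27 had a median of 38.6% in females and 19.7% in males, with male means from 4.92% to 33.3%, and 24 overlapped a named gene. The 74 had a median of 72.0% in females and 84.97% in males, with male means from 76.4% to 93.7%, and 51 overlapped a named gene. On autosomes 0 of 13586 windows passed by edgeR, with 179 at an unadjusted p under 0.05 when fitted alone. That count was below a share of 0.05 of the autosomal windows, the average without any difference, which decides little since windows are not independent. Outside X, 3 windows passed and were named after their values were seen: 1 on Y (start 25200001, higher in males by 10.9 points) and 2 on unplaced sequence, by 10.9 and -20.9 points, none with a named gene. Each female library listed 28 to 48 Y windows, with 0.0699% of calls on average, so the female values of the Y window come from calls that do not belong to a Y chromosome.

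**Figure D4:**
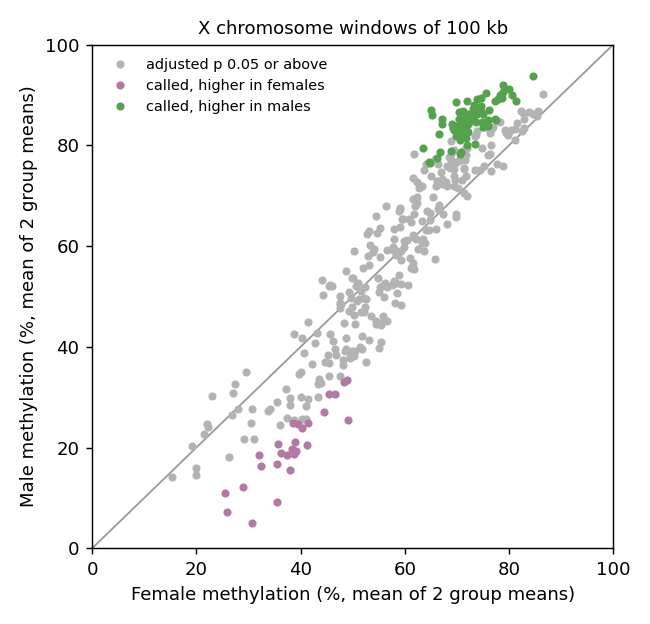
Mean methylation in males against females (%, each the mean of 2 group means) for the 378 X windows. Points above the line are higher in males; the 27 windows called higher in females have male means of 4.92% to 33.3%, and the 74 called higher in males 76.4% to 93.7%.

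Together, 104 windows passed for sex by edgeR, 76 higher in males and 28 higher in females, and with separate library sizes for methylated and unmethylated calls 143 passed, 87 and 56. With at least 500 calls in every animal 23 passed, with at least 10 calls in 20 of the 24 animals 194, and with no coverage filter 259. With global methylation as a covariate 156 passed. Within the 19 libraries of the chromosome 9 split 84 passed, 79 of them shared. Of list members, 1 rose from female to male in monoamine signalling, and 1 fell in the glucocorticoid axis and 1 in energy balance, counts that were 1 each adjusted over the list alone. A member each of the antiviral and the oligodendrocyte list rose only when adjusted over the list alone, and no list passed (smallest adjusted p = 0.499). Pooled methylation was 53.9% ± 8.74 in females and 54.5% ± 5.04 in males on autosomes (SD, n = 12 and 12; difference 0.260 points, p = 0.935, permutation test), and the difference ran from -1.57 points without control female 5 to 1.06 without control female 7. As a mean over windows it was 0.0513, from -1.12 without control female 5 to 0.603 without viral male 14. On X it was 58.8% ± 6.32 and 61.6% ± 6.52 (2.45 points, p = 0.363, permutation test), and the difference was 1.08 points without control female 5 and 1.49 without control male 9. As a mean over windows it was 0.934, from -0.105 without control female 5 to 1.75 without viral male 14.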

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

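The tests of window weights, mitochondrial methylation, male calls per X window, the chromosome 9 window and other splits of the animals were chosen after the results were seen. Of 412 groups of values, 42 held an animal far from the rest of its group, where chance gives about 1 in 20 (20.6 of 412), and 18 of the 42 concerned control female 5. Control female 5 was lowest of the control females in methylation over all calls (31.7%), as a mean over windows (39.8%), on autosomes (29.8%) and on X (40.6%). It was also lowest in windows of CSNK1D (41.0%), SLC39A11 (71.7%), TET1 with DNA2 (11.1%), AVP (14.8%), BBS9 (60%), MEGF11 (41.7%), CGA (67.1%), PCDH1 (30.7%) and DNMT3A (33.5%). The same held for DNMT3A with POMC (40.4%), CIITA (39.2%), SEMA4F (48.4%), DLK1 (38.4%) and BRINP2 (59.5%).

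The tables argue against calls drawn from windows of low methylation as the whole source, since with the same window weights in every animal control female 5 was at 38.987% and the lowest other animal at 49.665%. Such calls may account for a part, since without those weights control female 5 was at 31.7%. The windows of lowest methylation took 14.5% of its calls, against 11.5% in control male 11, the next highest animal. The tables argue against more complete bisulfite conversion of unmethylated cytosines, since mitochondrial methylation of control female 5 was 9.72% and the median of all animals 9.39%. Conversion of methylated cytosines is not measured by this value and was not tested. More fragments of unmethylated islands within each window may contribute: relative to the other animals, the median log2 odds was -0.62 in windows at least 85% methylated and -1.59 in windows of 40 to 60%, a ratio of 0.389, but also -0.67 in windows of at most 15%. That test was set before its result was seen, compared only the first of these levels with the second and was not specific to islands, so this explanation stays open. No biological explanation was tested, since the labels set this animal apart in nothing.

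X windows of low methylation were higher in females and those of high methylation higher in males. Calls from other copies placed on X in males are argued against: the male to female ratio of call shares was 0.266 in called and 0.268 in uncalled X windows, a quotient of 0.990. Fewer male calls per X window may add to the number of called windows and stay open. Of the X windows with fewer male calls 32.8% were called, against 20.6% of those with more. These windows were split by male calls alone and not matched for level, so the shares do not single out the number of calls. Both directions remained with at least 500 calls in every animal, where 23 windows passed for sex, 17 higher in males and 6 higher in females. Few calls alone therefore do not account for the pattern. The called differences followed the sex of the animals, which the design names. None of the windows called by edgeR was autosomal, and by limma the real split by sex far exceeded every other, as given below. How sex leads to the trend with level stays open. Across 277 uncalled X windows the male minus female difference rose with the mean level (Spearman 0.610), against 0.368 across autosomal windows. That extends the trend to windows below the threshold but does not single out sex as its source. By limma, 107 windows were called for sex, a count that 1 of 100 splits of the animals reached, the real one included. The highest other split called 8. Chance is therefore an unlikely source of that count, though 100 splits cannot exclude it.

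In the chromosome 9 window, 5 libraries held few calls at high methylation. A deletion reaching beyond the window in the 5 animals is argued against, since calls in its neighbours were at 1.18 times the level of the other 19, within 0.609 SD, against 0.0227 times in the window itself; this explanation was narrowed to deletions beyond the window after its result was seen, and a difference inside the window stays open. Unmethylated DNA counted there in the 19 stays open: the calls beyond the level of the 5 were at most 4.27% methylated in any of them, which restates the low methylation of the 19 and supports nothing. A library batch stays open: the 5 were parted from the rest in 7 autosomal windows by share of calls and in 9 by methylation, which 5 and 2 of 100 random sets of 5 reached, and their mitochondrial methylation lay outside the 8.97% to 10.8% of the other 19. The 5 also hold the last numbers of each arm, and the labels do not say what the numbers follow. Since 4 of the 5 were viral, this split stays partly confounded with the arms.

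In the other contrasts limma called 0 windows, which 100 of 100 splits must reach, so that count tests nothing. At an unadjusted p under 0.05, 35 of 100 splits gave as many windows as the 457 for infection, 56 as many as the 296 for the difference between sexes, 35 as many as the 734 in females and 90 as many as the 185 in males, so chance cannot be excluded for these counts. The highest other split called 1 window for infection, 3733 for the difference between sexes, 2167 in females and 10 in males. The counts of 3733 and 2167 came from 1 split each and may reflect a structure of the samples; which animals these splits group was not examined.

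The remaining animals lay apart in single values and are not weighed here. Control male 9 was highest in its group over TET1 with DNA2 (33.7%), TET1 with CCAR1 (88.6%), CARTPT (66.2%), SIX6 (40.4%) and DLK1 (59.7%), and lowest over GABBR2 (73.3%). Control male 13 was lowest in mitochondrial methylation (8%) and over IGF1R (79.0%). Control male 11 was lowest over CAPZA1 (12.2%), JAK1 (81.6%) and AAMDC with INTS4 (82.4%). Control male 12 was highest over CGA (82.2%), SLA-DRB1 (68.4%) and NR0B1 (14%). Control female 3 was highest over SRD5A2 (21.9%) and control female 4 over CFAP54 (87.2%). Viral female 18 was lowest over ASPA (70.7%) and DNMT1 (29.5%), and viral female 24 over BBS9 (86.0%). Viral males 17 and 20 were highest over MBD4 (64.9%) and PCMT1 (25.4%), and viral male 23 was lowest over SLC4A4 (17.7%). Viral male 21 was lowest over NR3C1 (84.7%) and highest over RUNDC3B (44.3%).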

How the results depend on the processing

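The minimum of 500 calls, the 2 alternatives built on the chromosome 9 window, X minus autosomes, the same window weights, exact enumeration, fry, limma for female with male effects and the fit without control female 5 with the methylation covariate were chosen after seeing the data. For infection, DESeq2 and the likelihood ratio test of edgeR each called 1 window, as did the fit with no coverage filter; in the remaining alternatives the count was 0. The TMEM178B window was higher in the viral arm in each alternative run, with adjusted p from 0.0360 to 1.0. In males the same 3 alternatives called 1 window each, and the fit with no filter called 1 for the difference between sexes. For sex, 0 windows passed on autosomes alone, which leave out X, 194 with calls in 20 of the 24 animals, 259 with no filter and 23 with at least 500 calls; fewer or more windows were tested in these. Leaving out each animal gave 96 to 114. X minus autosomes was 2.19 points (p = 0.0285, permutation test; Benjamini-Hochberg 0.900), but 0.883 as means over windows (p = 0.147, permutation test) and 1.52 in the 19 libraries (p = 0.199, exact permutation test; 0.948 without viral female 16), against 2.45 points for X. As means over windows in the 19 libraries X minus autosomes was 0.377, from -0.125 without viral female 16 to 0.873 without viral female 18.

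Of the values of single windows, 4084 kept their direction and side of the threshold, 4 newly passed, 1 no longer passed and 30 changed direction. The changes of direction were in windows that did not pass. With overall methylation as a covariate, log2 odds were -0.112 for DNMT1 (start 68900001), -0.0584 for DNMT3A and -0.153 for TET1 with CCAR1, and also without control female 5 -0.108, -0.0608 and -0.142. With separate library sizes they were -0.124 for DNMT1, -0.0942 for DNMT3A and -0.0835 for CRH. With the chromosome 9 covariate they were -0.0288 for DNMT1 and -0.00527 for TET1 with CCAR1. In the 19 libraries they were -0.102 and -0.0128 for the DNMT1 windows and -0.233 for TET1 with CCAR1. DNMT3B was at 0.000393 with limma and an offset of 5. Leaving out each animal, values ran from -0.0371 to 0.128 for DNMT1, -0.0966 to 0.0612 for DNMT3B, -0.00500 to 0.175 for CRH and -0.0150 to 0.119 for DNMT3A. Autosomal methylation by sex ran from -1.57 to 1.06 points. The cause was not tested. Minimums of 5 and 30 calls removed no window and test nothing, since no listed window had fewer than 100 calls.

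Counts at an unadjusted p under 0.05 moved by over 1.5 times when certain animals were left out. For infection, 419 became 675 without control female 7, 258 without control male 11, 691 without viral male 14, 877 without viral female 18 and 258 without viral female 22. For sex, 391 became 770 without control female 5. For the difference between sexes, 245 became 395 without control female 7, 148 without control male 9, 572 without viral female 18 and 158 without viral female 22. In females, 657 became 298 and 1218 without control females 5 and 7, and 368, 1660, 327 and 427 without viral females 16, 18, 22 and 24. In males, 143 became 246 without control female 5 and 215 without viral male 14.

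Other settings moved them as far. With overall methylation as a covariate they became 644 for infection, 1081 for sex, 528 for the difference between sexes and 593 in males, and also without control female 5 644, 1030, 529 and 592. With separate library sizes they became 657, 787, 436 and 420, and with no coverage filter 714, 900, 494 and 403. With at least 500 calls they became 258, 130, 138 and 44. With calls in 20 of the 24 animals they became 622 for sex and 236 in males, and on autosomes alone 179 for sex. With the chromosome 9 covariate they became 219 for infection and 325 in females, in the 19 libraries 141 and 180, and with only the 2 groups 376 in females.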

Other observations

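The levels of the lists, set against 10000 random lists matched on calls, were compared after the data were seen and take no account of CpG density. The random lists drew on all tested windows, 2656 of them without a named gene, and windows of the same gene were counted separately. The percentiles therefore do not set these genes apart from other genes. Of the 24 lists, 17 lay below the median of their random lists and 7 above, 9 under percentile 5 and 1 over percentile 95. Windows of protocadherin and HOX genes had a median methylation of 12.8%, against a median of 56.9% over the random lists. Hypothalamic development genes were at 22.4% (random 52.2%), GABA signalling at 32.1% (random 60.8%) and the circadian clock at 36.3% (random 58.1%). Glutamate signalling, neurons, the glucocorticoid axis, DNA methylation machinery and neuropeptides were at percentiles 0.07, 1.91, 2.69, 3.06 and 4.9. Axon guidance and adhesion genes were at 68.4% (random 58.8%), at percentile 98.95. Mitochondrial methylation differed by -0.402 points between the arms (p = 0.426, permutation test; Benjamini-Hochberg 0.900 over 35 tests), from -0.724 without viral male 23 to -0.161 without viral male 21. The difference was -1.01 points in females (p = 0.0922, exact permutation test) and 0.202 in males (p = 0.844, exact permutation test). Within the 19 libraries of the chromosome 9 split it was -0.261 points.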
